A study of Homo sapiens with 18 samples.

How the data were processed

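RNA-seq of SCC25 cells was analysed in 18 libraries, 3 in each of 6 groups (control or FBW7-knockout cells, given DMSO, 1,25D or ATRA). Total RNA was extracted and polyadenylated RNA was enriched for the libraries, per the labels' protocols. The values were counts of reads per gene, whole numbers without normalization, in 1 table deposited by the authors with a column per library and 27773 gene symbols. The submitters' processing notes name FastQC, HISAT2 and featureCounts and the genome build GRCh38 (hg38). Tool versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, genes that overlap a gene on the other strand (such as FEZF1-AS1) cannot be told from it, and genes with near-identical copies (KRT16, CBS, U2AF1, AKR1C1, HES4, genes of the major histocompatibility region) may share or lose reads. Each column was tied to its sample by the column name that the sample's label states. Of the symbols, 27629 matched a RefSeq gene of GRCh38.p14, as did 16352 of those tested, and gene positions are from that annotation.

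Library totals were 45275080 to 73349849 counts. Replicates of 1 group differed by more than counting noise in every pair (chi-square per gene 3.34 to 12.5 over genes with a mean count of at least 100), so no 2 libraries were treated as 1. CPM values are counts scaled to a common library size with TMM factors, given as mean ± SD.

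Genes were kept by filterByExpr of edgeR (minimum count 10), which left 16435. All 18 libraries entered a single quasi-likelihood fit with 1 mean per group (R 4.3.3, edgeR 4.0.16, TMM factors, robust; 12 residual and a median of 26.1 prior degrees of freedom). The common biological coefficient of variation was 3.89%. The contrasts, tested 2-sided, were knockout against control in DMSO, each ligand against DMSO in each cell type, and the difference between the knockout and the control response to each ligand, 7 in all. p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, and a gene was called at an adjusted p below 0.05. Errors of log2 changes are SEs, computed as the log2 change divided by the square root of the F statistic. Where a group has few counts, such an SE may be too small. A gene with a total of 1 to 3 counts in a group is given as a ratio of counts with its 95% interval, and against 0 counts as a bound from 3 counts over the group. These cover counting error only, since reads without molecular identifiers are not independent molecules.

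There were 19 gene lists, holding 543 genes of which 34 were in more than 1 list. They were tested with camera (limma 3.58.1, voom values, preset correlation 0.01, adjusted over the lists of a contrast) and again with the correlation estimated from the data. Members called were counted over all genes and adjusted over the list alone. Weakening was tested with fry on the difference contrast, signed by the average response, over genes whose average response was called. The average and the difference are orthogonal in this balanced design. Principal components used log2 CPM with a prior count of 2. Figures were drawn with matplotlib 3.10.9.

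Genes named were chosen by rule. FBXW7 came first. For each contrast there were the 8 genes with the largest positive and the 8 with the largest negative change among those called, with a mean of at least 1 CPM and, in 2-group contrasts, no overlap of replicates (clone-style, LOC and pseudogene names left out). CYP24A1, CYP26A1, VDR, RARA, RARB, RXRA, MYC, CCNE1, JUN and NOTCH1 could be named in every contrast, and up to 4 members per list with the smallest adjusted p, 2 higher and 2 lower where both existed. Members that did not pass could be named where their list was described. VARS1, CLIC1, YTHDC1 and ITPK1, which vary many-fold within groups, came under this rule. Some genes that the rule names are not reported here. The groups, contrasts, tests of the contrasts and lists, naming rule and most alternatives were fixed before the data were examined. Chosen after were the regional-block position test, the GC-content and length trend, the non-responding-fraction test, the test of genes with like DMSO levels, the shared-copies test, the sampling-noise test, 2 tests of MYC mRNA, removal of the median of 20-Mb windows, thinning of all libraries to the smallest total, RLE scaling of the weakening test and the 0.01 threshold for named genes.

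Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter (1 CPM in 6 libraries), only the groups of the contrast, the replicate number as a block, an adjusted p below 0.01, a test against a 1.5-fold change, and each library left out in turn. Genes to which DESeq2 gave no adjusted p were kept without one. The tests of genes, lists and weakening were run on simulated counts, drawn around each gene's mean over all 18 libraries, with the libraries' sizes. Genes were drawn independently, and no knockout effect was put in. With 50 genes changed at each fold, the 1,25D contrast of control cells recovered 78%, 88%, 96% and 100% at 1.25-, 1.5-, 2- and 4-fold, with 17 false calls among 198 (16137 genes). The 1,25D difference contrast recovered 56%, 76%, 84% and 100%, with 8 false calls among 166. A simulated list of 30 genes shifted 1.25-fold was found by camera (adjusted p = 1.2e-145) and 0 of 19 random lists were called (16130 genes). With independent genes this does not test camera on correlated ones. Simulation of the weakening test is described with its result. Its first draw was the one with a share of 54.3% and a fry p of 0.00056, after which 20 further draws were added.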

Results

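Gene expression was measured by sequencing of polyadenylated RNA from SCC25 cells, a line derived from a human squamous cell carcinoma of the tongue. Control cells and cells in which FBW7 had been knocked out were each given vehicle (DMSO), 100 nM 1,25-dihydroxyvitamin D (1,25D, the hormonal form of vitamin D) or 100 nM all-trans retinoic acid (ATRA, a vitamin A metabolite) for 16 h. FBW7, encoded by FBXW7, is the substrate-recognition subunit of a ubiquitin ligase whose reported substrates include MYC, cyclin E, JUN and the intracellular part of NOTCH1. Both ligands act through nuclear receptors, the vitamin D receptor (VDR) and the retinoic acid receptors, which pair with retinoid X receptors on DNA. The 6 groups held 3 libraries each, 18 in all. Total gene counts ran from 45275080 in control 1,25D replicate 1 to 73349849 in FBW7-knockout ATRA replicate 3, and 16435 of 27773 genes had enough counts to be tested. Mitochondrial transcripts took 3.31% ± 0.373 of the counts in control DMSO libraries, 3.85% ± 0.474 under 1,25D and 3.54% ± 0.352 under ATRA (SD, n = 3). The shares in the knockout were 4.24% ± 0.260, 4.62% ± 0.364 and 4.49% ± 0.531 in the same order. The labels tie the RNA to 3 isolates without saying whether these were separate cultures, so p-values measure the spread between these samples, which may be technical. Whether the knockout was a clone or a pool is not given in the sources used here. The p-values do not measure spread between separate knockouts, and differences from control may have sources other than loss of FBW7.

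The first principal component of log2 CPM (counts scaled to library size) carried 52.6% of the variance and parted the knockout libraries from the control libraries. The second carried 22.9% and set 1,25D apart from DMSO and ATRA on the other side, with the 3 libraries of each group close together.

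**Figure D1:**
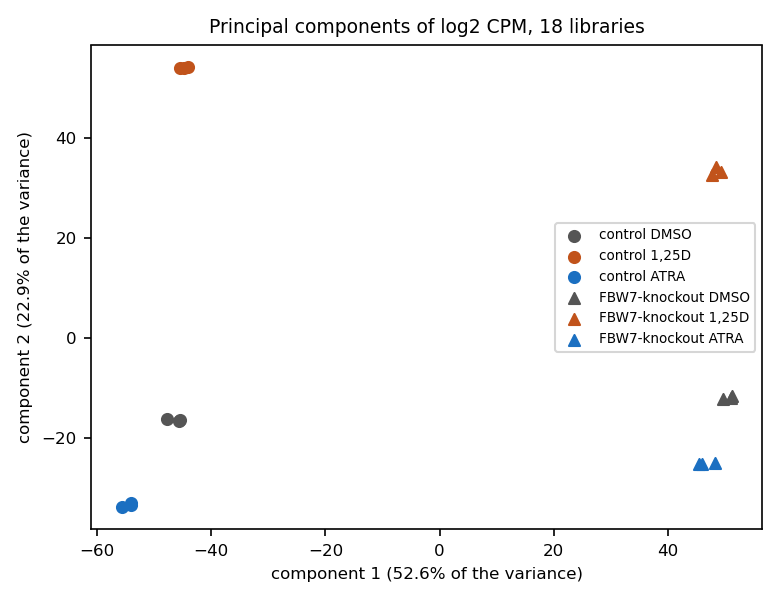
Principal components of log2 CPM over the 16435 tested genes, with 1 point per library (18 libraries, 6 groups). The x axis is the first component (52.6% of the variance) and the y axis the second (22.9%).

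FBXW7 (chromosome 4, 152320544 to 152536092, GRCh38.p14) was lower in every knockout library than in any control library. The 3 control DMSO libraries held 27.8, 27.9 and 26.4 CPM, the control 1,25D libraries 31.7, 31.9 and 32.1 CPM, and the control ATRA libraries 22.1, 23.2 and 23.3 CPM. In the knockout the DMSO libraries held 16.8, 16.7 and 14.7 CPM, the 1,25D libraries 16.9, 17.9 and 16.8 CPM, and the ATRA libraries 13.7, 15.3 and 15.2 CPM. The log2 change between knockout and control was -0.77 ± 0.05 in DMSO, -0.89 ± 0.05 in 1,25D and -0.63 ± 0.05 in ATRA (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, largest adjusted p = 9.31e-15), which is 1.70-fold, 1.85-fold and 1.55-fold lower. The direction went with the labels in all 18 libraries. The position of the edit is not given in the sources used here, and transcript reads can remain when the protein is lost, so these values do not measure the protein.

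**Figure D2:**
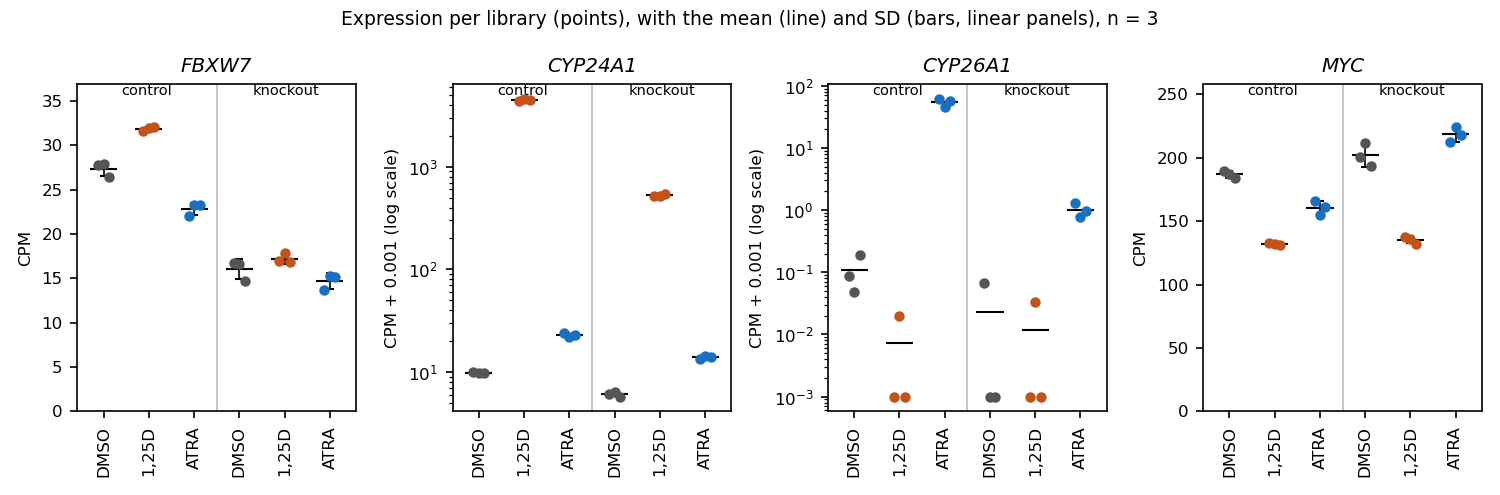
CPM of FBXW7, CYP24A1, CYP26A1 and MYC in each library (points, n = 3 per group) with the group mean as a line, and SD bars in the linear panels; CYP24A1 and CYP26A1 are on a log scale of CPM + 0.001. FBXW7 lies at 13.7 to 17.9 CPM in the 9 knockout libraries and at 22.1 to 32.1 CPM in the 9 control libraries.

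The first comparison asked how gene expression differs between knockout and control cells given vehicle. Among genes with a mean of at least 1 CPM the largest increases were in ESM1, a secreted proteoglycan (6.54 ± 0.13, log2 ± SE), CYB5A, cytochrome b5 (5.55 ± 0.19), and RNF182, a ubiquitin ligase (5.06 ± 0.22). MARCHF4, a membrane-bound ubiquitin ligase, went from 1.85 ± 0.0985 to 45.1 ± 1.56 CPM (SD, n = 3), and the monocarboxylate transporter family member SLC16A9 (4.21), the Wnt receptor FZD3 (4.08), the ferroxidase HEPHL1 (4.02) and the matrix protein FBLN5 (3.87 ± 0.33) rose by a similar amount. Losses included MPPED2 (-9.11), the cancer-testis antigen MAGEA11 (-7.56 ± 0.30) and GNE, the first enzyme of sialic acid synthesis (-6.64 ± 0.17). The proteoglycan BGN (-6.48 ± 0.29) and the ephrin receptor EPHA3 (-6.43 ± 0.27) fell too. MPPED2 had 4 counts over the 3 knockout DMSO libraries, too few for its SE to be given. The largest adjusted p among these genes was 3.18e-10 by edgeR's quasi-likelihood test. Counts of 3 other genes were almost gone from the knockout, namely FAM133A (1 count over 3 libraries against 961, 831-fold lower, 95% counting interval 149 to 32860), SHROOM4 (2 against 1595, 690-fold, 191 to 5700) and UBXN10 (2 against 450, 195-fold, 53.6 to 1612). Such intervals cover counting error only.

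Genes were grouped by 19 lists fixed beforehand, and counts of called members adjusted over the list alone were those over all genes, in each comparison, except where both are given. Interferon-stimulated genes fell almost throughout: of 30 measured, 0 rose, 28 fell and 2 were not called (median -1.36, camera adjusted p = 1.17e-14, and adjusted p = 0.205 with estimated correlation). IFI44 (-1.65; chromosome 1, 78649789 to 78664078), SAMD9 (-1.34), the ISG15 ligase HERC5 (-2.48) and the antiviral factor TRIM22 (-2.77) were among them (edgeR, largest adjusted p 1.71e-25). Cell-cycle transcripts were lower too. Of 32 S phase genes 5 rose, 26 fell and 1 was not called (median -0.28, camera adjusted p = 4.67e-05, and adjusted p = 0.205 with estimated correlation), with the replicative helicase subunit MCM7 at -0.92 against a rise of RRM2, a subunit of ribonucleotide reductase (0.37). Of 30 G2 and mitosis genes 1 rose, 28 fell and 1 was not called (median -0.32, camera adjusted p = 1.82e-09, and adjusted p = 0.205 with estimated correlation), with the spindle gene ASPM at -1.07 and the mitotic kinase NEK2 at -1.21, while CDK1 alone rose (0.21). Retinoic acid receptor targets went the same way: 6 rose, 19 fell and 5 were not called (median -0.42, camera adjusted p = 0.0487, and adjusted p = 0.499 with estimated correlation), among them ASCL2 (-1.69) and RARG (-0.78), against a rise of BHLHE40 (0.89). Over these genes the largest edgeR adjusted p was 4.41e-08.

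Immediate early and inflammatory genes moved up. Among 24 AP-1 and immediate early genes 17 rose, 4 fell and 3 were not called (median 0.64, camera adjusted p = 0.000573, and adjusted p = 0.205 with estimated correlation). IER2 (0.79), KLF6 (1.29) and JUN (0.44 ± 0.03) rose while EGR1 fell (-1.39). Among 23 NF-kB and inflammatory cytokine genes 17 rose, 2 fell and 4 were not called, or 17 and 3 over the list alone (median 0.71, camera adjusted p = 0.00183, and adjusted p = 0.205 with estimated correlation). The cytokine IL1B (1.66) and the NF-kB inhibitor TNFAIP3 (1.20) rose, the adhesion molecule ICAM1 fell (-0.88), and CSF3 went from 131 counts to 2 (56.6-fold lower, counting interval 15.4 to 473). The largest edgeR adjusted p among these genes was 8.12e-05. None of the 6 camera calls of the knockout comparison, these included, held with the estimated correlation.

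The other 13 lists were not called as sets by camera. Among 35 vitamin D receptor targets 12 rose, 19 fell and 4 were not called (median -0.27, camera adjusted p = 0.359), with the cell-cycle inhibitor CDKN1A at 1.23 and the growth-factor binding protein IGFBP3 at -1.64, and the median was -0.34 with members near 0 counts at their counting estimate. Of 26 cornified envelope genes 7 rose, 9 fell and 10 were not called (median 0.05, camera adjusted p = 0.415), where the median was positive while the mean (-0.16) and the test pointed down. The desquamation proteases KLK5 (-4.23, chromosome 19, 50943303 to 50953038) and KLK7 (-2.95) were among the falls and PRDM1 (0.89) was among the rises. Of 22 basal keratinocyte and hemidesmosome genes 14 rose, 6 fell and 2 were not called (median 0.16, camera adjusted p = 0.101), from the laminin chain LAMA3 (1.05) to SOX2 (-2.12). The 58 MYC-associated growth genes were divided: 22 rose, 27 fell and 9 were not called, or 23 and 27 over the list alone (median -0.01, camera adjusted p = 0.668). MCM4 rose (0.62) and AIMP2 fell (-0.87). Of 20 Notch genes 9 rose, 6 fell and 5 were not called, or 10 and 6 over the list alone (median 0.35, camera adjusted p = 0.480), with the ligand JAG1 up (0.89) and the modifier LFNG down (-1.86). Among 33 sterol and fatty acid synthesis genes 16 rose, 9 fell and 8 were not called (median 0.09, camera adjusted p = 0.422), including ACLY (0.79) and EBP (-1.58). Of 25 NRF2 and redox genes 12 rose, 8 fell and 5 were not called (median 0.04, camera adjusted p = 0.506), with a mean of -0.01 against a positive median and test. Of 28 hypoxia and glycolysis genes 14 rose, 8 fell and 6 were not called (median 0.13, camera adjusted p = 0.359), with P4HA1 at 1.03 and ENO2 at -1.79. For the genes named here the largest edgeR adjusted p was 5.93e-13.

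Markers of other cell types moved as well. Carcinoma cells can also express them, and which cells held these transcripts was not tested. Among 26 mesenchymal and fibroblast markers 9 rose, 16 fell and 1 was not called (median -0.53, camera adjusted p = 0.359), with the actin-binding TAGLN up (2.32) and the collagen COL3A1 (-5.47) and LUM (-4.38) down. Among 11 leukocyte and endothelial markers 0 rose, 5 fell and 6 were not called (median -0.9985, camera adjusted p = 0.101), with CD68 at -0.57 and PECAM1 going from 30 counts to 3 (8.65-fold lower, counting interval 2.69 to 44.3). For 14 antimicrobial genes 7 rose, 6 fell and 1 was not called (median 0.13, camera adjusted p = 0.868), with a mean of -0.10 and a median of 0.26 once members near 0 counts were set to their counting estimate; LCN2 fell (-2.79) and RNASE7 rose (0.76). The transcripts of 32 reported FBW7 substrates went both ways: 12 rose, 12 fell and 8 were not called (median 0.01, camera adjusted p = 0.530), with a mean of -0.21. Of these, MYC (0.11 ± 0.03; chromosome 8, 127735434 to 127742951), CCNE1 (0.29 ± 0.07), NOTCH1 (0.30 ± 0.05) and NFKB2 (0.35) rose and CCNE2 (-0.97) and AURKA (-0.59) fell. Among 33 nuclear receptors, partners and cofactors 10 rose, 14 fell and 9 were not called (median -0.08, camera adjusted p = 0.365). VDR (-0.20 ± 0.03), RXRA (-0.42 ± 0.02) and RARB (-1.88 ± 0.33) were lower and RARA was level (0.03 ± 0.04, adjusted p = 0.500). The largest edgeR adjusted p among the other genes named here was 0.00103.

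In all, 11390 genes differed between knockout and control in DMSO (5788 higher, 5602 lower; edgeR, adjusted p below 0.05), 766 of them by 2-fold or more upward and 1356 downward. The replicates of the 2 groups did not overlap for 71.6% of genes, against 10% by chance for 3 against 3. The same comparison gave 11415 genes in 1,25D and 11783 in ATRA, and 8533 genes changed the same way in all 3 treatments. Shifts tended to run in blocks along chromosomes. In 21 of 147 windows of 20 Mb at least 80% of the measured genes were shifted one way, against 1 in the highest of 100 shuffles of gene positions, for example a median of -0.69 on chromosome 1 from 200 to 220 Mb and 0.65 on chromosome 7 from 140 to 160 Mb. No window passed that limit in any of the 4 ligand responses. Some genes named above lie in windows with lowered medians. These were MCM7 (-0.35; chromosome 7, 100 to 120 Mb), AIMP2 (-0.35; chromosome 7, 0 to 20 Mb), CCNE2 (-0.46; chromosome 8, 80 to 100 Mb) and EBP (-0.85; chromosome X, 40 to 60 Mb). CDK1 rose by less than the median of its window (0.32; chromosome 10, 60 to 80 Mb). Part of the change of such genes may therefore be regional.

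**Figure D3:**
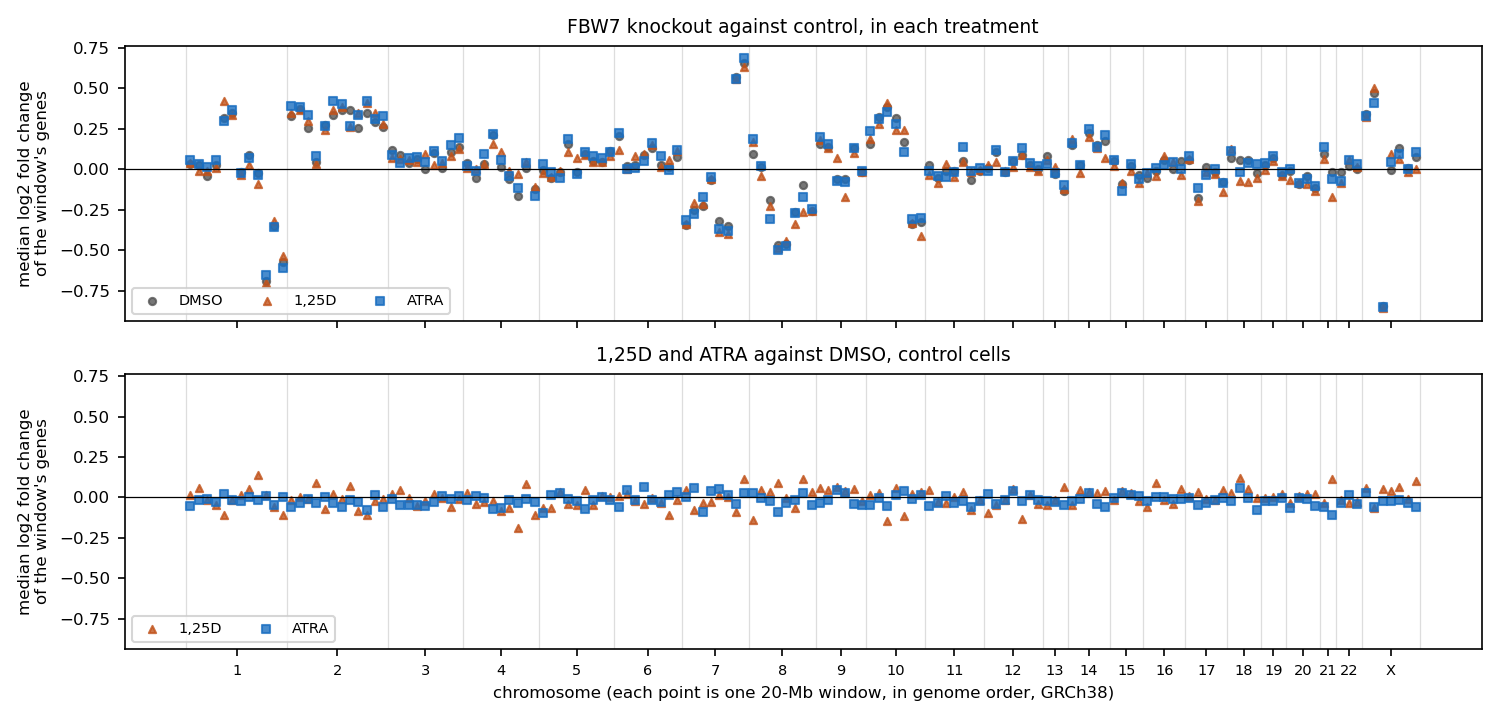
Median log2 fold change of the genes in each of 147 windows of 20 Mb, in genome order (x axis), for the knockout effect in DMSO, 1,25D and ATRA (top) and for the 1,25D and ATRA responses of control cells (bottom). The knockout medians follow one another across treatments, and the ligand medians stay near 0.

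The next comparison asked how control cells respond to 1,25D. CYP24A1, the hydroxylase that inactivates 1,25D (chromosome 20, 54143538 to 54173986), rose from 9.81 ± 0.101 to 4464 ± 72.6 CPM (SD, n = 3), a log2 change of 8.83 ± 0.04 (edgeR adjusted p = 3.32e-57). The cannabinoid receptor CNR1 (7.63 ± 0.24), the organic anion transporter SLCO1A2 (6.62 ± 0.08), the scavenger receptor COLEC12 (6.59 ± 0.28) and the drug-metabolising CYP3A5 (6.25 ± 0.14) followed. Genes that fell included TMEM52B (-4.33 ± 0.15), the interferon-induced chemokine CXCL10 (-3.80 ± 0.19), the oxidised lipoprotein receptor OLR1 (-3.32 ± 0.06), the Wnt ligand WNT16 (-3.25 ± 0.22), ANKRD1 (-3.14 ± 0.10) and the receptor phosphatase PTPRZ1 (-2.82 ± 0.08). The largest adjusted p among these genes was 7.14e-15 by edgeR's quasi-likelihood test. MYC (-0.50 ± 0.03) and VDR itself (-0.50 ± 0.03) fell, as did RARB (-3.50 ± 0.41), the beta form of the retinoic acid receptor (largest adjusted p 1.72e-09, edgeR).

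Vitamin D receptor targets rose as a set: of 35, 30 rose, 2 fell and 3 were not called (median 1.22, camera adjusted p = 3.52e-17, and 0.00285 with estimated correlation), including SEMA3B, a secreted semaphorin (5.22). MYC-associated growth genes fell: of 58, 1 rose, 55 fell and 2 were not called (median -0.47, camera adjusted p = 6.19e-24, and 0.00285 with estimated correlation), among them the ribosome-assembly gene NOLC1 (-0.62) and UNG, a DNA repair glycosylase (-0.81). S phase genes fell as well: 0 rose, 30 fell and 2 were not called (median -0.40, camera adjusted p = 2.25e-15, and 0.00331 with estimated correlation), with MCM2 at -0.57 and MCM10 at -0.73. These 3 calls held with the estimated correlation, and 10 further camera calls did not. Of G2 and mitosis genes 0 rose, 27 fell and 3 were not called (median -0.20, camera adjusted p = 2.31e-07, and adjusted p = 0.208 with estimated correlation), with CCNA2 at -0.41. Of interferon-stimulated genes 1 rose, 27 fell and 2 were not called (median -0.63, camera adjusted p = 1.17e-11, and adjusted p = 0.160 with estimated correlation), with OASL at -1.21. Of NF-kB genes 4 rose, 14 fell and 5 were not called (median -0.58, camera adjusted p = 0.0423, and adjusted p = 0.254 with estimated correlation). PTGS2, the inducible cyclooxygenase (1.72), and NFKBIA (0.48) rose and CXCL1 (-1.29) fell. Notch genes leaned down: 4 rose, 10 fell and 6 were not called (median -0.32, camera adjusted p = 0.0417, and adjusted p = 0.160 with estimated correlation). JAG1 was at -0.77 and HES1 at 0.41. The edgeR adjusted p was at most 2.80e-11 for these genes.

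Several epithelial and metabolic lists rose under 1,25D. Of AP-1 genes 18 rose, 5 fell and 1 was not called (median 0.46, camera adjusted p = 6.78e-05, and adjusted p = 0.0978 with estimated correlation). JUNB (1.08) and JUND (-0.63) were among them. Of basal keratinocyte genes 14 rose, 5 fell and 3 were not called (median 0.23, camera adjusted p = 0.00357, and adjusted p = 0.192 with estimated correlation). LAMB3 was at 1.00 and SOX2 at -0.84. Of sterol synthesis genes 20 rose, 5 fell and 8 were not called (median 0.19, camera adjusted p = 0.000867, and adjusted p = 0.166 with estimated correlation). FADS1 was at 0.87 and ELOVL6 at -0.97. Of hypoxia genes 16 rose, 6 fell and 6 were not called (median 0.18, camera adjusted p = 0.0162, and adjusted p = 0.160 with estimated correlation), with BNIP3L at 0.90. Of NRF2 genes 13 rose, 6 fell and 6 were not called (median 0.17, camera adjusted p = 0.0249, and adjusted p = 0.249 with estimated correlation). Of cornified envelope genes, also called upward, 11 rose, 3 fell and 12 were not called (median 0.52, camera adjusted p = 0.0423, and adjusted p = 0.249 with estimated correlation). Among these the calmodulin-like CALML3 rose (1.17) and the crosslinking enzyme TGM1 (-1.25) and filaggrin FLG (-2.33) fell, FLG from 58 counts to 2 without control 1,25D replicate 3 (13.9-fold lower, counting interval 3.69 to 118). The largest edgeR adjusted p among these genes was 0.000303. The antimicrobial list missed the threshold: 8 rose, 5 fell and 1 was not called (median 1.04, camera adjusted p = 0.0544). CD14, a co-receptor for bacterial lipopolysaccharide, was at 2.39 and the epithelial cytokine TSLP at 3.47. Retinoic acid receptor targets were not called (8 rose, 15 fell and 7 were not called, or 8 and 17 over the list alone (median -0.18, camera adjusted p = 0.240)), with DHRS3 at -2.05 and CRABP2 at -1.68 (edgeR, largest adjusted p 2.19e-19). Altogether 9470 genes were called (4826 higher, 4644 lower), 754 higher and 492 lower by 2-fold or more, with no overlap of replicates for 62.6% of genes against 10% by chance. CYP26A1 fell from 23 counts to 1 (18.4-fold lower, counting interval 2.99 to 758, edgeR adjusted p = 0.0394), a call lost without control DMSO replicate 1 or 3 (adjusted p = 0.053 and 0.143) and without control 1,25D replicate 1, 2 or 3 (adjusted p = 0.0926, 0.0646 and 0.127). Its 1 count in 1,25D lay in replicate 2, without which the fall was at least 4.11-fold, with 3 counts over the group as the floor. In the other 4 cases the fall was 11.1- to 20.5-fold, with counting intervals between 1.56 and 857.

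The response of control cells to ATRA was led by CYP26A1, the hydroxylase that clears retinoic acid (chromosome 10, 93073475 to 93077885). It rose from 0.108 ± 0.0736 to 54.5 ± 7.30 CPM (SD, n = 3), a log2 change of 8.91 ± 0.27 (edgeR adjusted p = 2.82e-12). Its DMSO level rested on 23 counts over 3 libraries, so this SE may be too small. The epithelial transcription factor ELF3 (4.30 ± 0.10), the retinol uptake receptor STRA6 (4.02 ± 0.10), the integrin ITGB3 (3.64 ± 0.10) and CNR1 (3.32) rose. The neurotensin receptor NTSR1 (-2.93 ± 0.21), the chemokine CXCL14 (-2.62 ± 0.12), the cytokine IL24 (-2.52 ± 0.13) and CASP14, a caspase of the epidermis (-2.001 ± 0.21), fell. By edgeR the largest adjusted p among these genes was 1.15e-10. CYP24A1 (1.23 ± 0.04) and RARB (1.32 ± 0.25) rose and MYC fell (-0.22 ± 0.03; largest adjusted p 3.49e-05, edgeR). KRT16 (-2.22 ± 0.19) is close in sequence to other keratin genes and may share reads with them, which would leave its value uncertain.

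Retinoic acid receptor targets rose: of 30, 22 rose, 4 fell and 4 were not called (median 0.91, camera adjusted p = 2.42e-14, and 0.00980 with estimated correlation), with the retinaldehyde reductase DHRS3 at 2.26 and HOXA3 at 1.98 against ASCL2 at -1.03. Basal keratinocyte genes fell: of 22, 1 rose, 18 fell and 3 were not called (median -0.34, camera adjusted p = 5.14e-11, and 0.0119 with estimated correlation), with the integrin ITGA6 at -1.19 and keratin KRT5 at -0.83. MYC-associated growth genes fell: of 58, 2 rose, 49 fell and 7 were not called, or 2 and 53 over the list alone (median -0.27, camera adjusted p = 1.01e-17, and 0.00980 with estimated correlation), including hexokinase HK2 (-1.08) and the chaperone HSPD1 (-0.36). These 3 calls held with the estimated correlation, and 5 others did not. Vitamin D receptor targets rose on balance: 18 rose, 5 fell and 12 were not called, or 19 and 6 over the list alone (median 0.39, camera adjusted p = 0.000942, and adjusted p = 0.162 with estimated correlation). IGFBP3 was at 1.72 and KLK6 at 2.08. Sterol synthesis genes did too: 15 rose, 4 fell and 14 were not called, or 16 and 5 over the list alone (median 0.05, camera adjusted p = 0.0150, and adjusted p = 0.394 with estimated correlation), with FADS2 at 0.85. Of G2 and mitosis genes 13 rose, 2 fell and 15 were not called (median 0.06, camera adjusted p = 0.0211, and adjusted p = 0.708 with estimated correlation). Hypoxia genes leaned down: 8 rose, 17 fell and 3 were not called (median -0.13, camera adjusted p = 0.0150, and adjusted p = 0.162 with estimated correlation). CA12 was at -1.12 and NDRG1 at -1.13. Of mesenchymal markers 5 rose, 12 fell and 9 were not called, or 5 and 13 over the list alone (median -0.29, camera adjusted p = 0.0150, and adjusted p = 0.162 with estimated correlation), with VIM at -1.01. The edgeR adjusted p reached 1.44e-14 at most among these genes. Median, mean and test differed in sign for 3 lists that were not called: S phase (median 0.03, mean -0.01, test up), FBW7 substrates (-0.02, 0.05, up) and nuclear receptors (-0.01, 0.47, up).

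ATRA changed 7488 genes in control cells (3642 higher, 3846 lower; edgeR), 468 higher and 191 lower by 2-fold or more, with no overlap of replicates for 53.6% of genes against 10% by chance. VARS1, which lies in the major histocompatibility region and varied many-fold within groups, was called (-4.11, adjusted p = 0.0181), but not without control ATRA replicate 1 (-4.11, adjusted p = 0.0548), 2 (-4.09, adjusted p = 0.0547) or 3 (-4.13, adjusted p = 0.058). Both ligands were compared with the same DMSO libraries. Of 5439 genes called in both responses, 3611 (66.4%) moved the same way, 1619 higher and 1992 lower, where independent lists would share 1069 and 1087. Across genes, which are not independent replicates, the fold changes had r = 0.122 and a covariance of 0.0414. In 20 simulations of unchanged groups against these controls the mean r was 0.473, the mean covariance 0.0169 (highest 0.0209), and no gene was called in both. The 3 control libraries cannot be split into parts of 2, so part of the excess may come from the shared controls. In knockout cells 1415 of 2574 genes called in both responses (55.0%) moved the same way. Of these 614 were higher and 801 lower, where independent lists would share 395 and 476. The other genes moved opposite ways: 594 rose under 1,25D and fell under ATRA, and 565 did the reverse. In control cells these numbers were 942 and 886. What independent lists would give for opposite moves was not computed, so the excess alone does not show a shared direction.

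**Figure D4:**
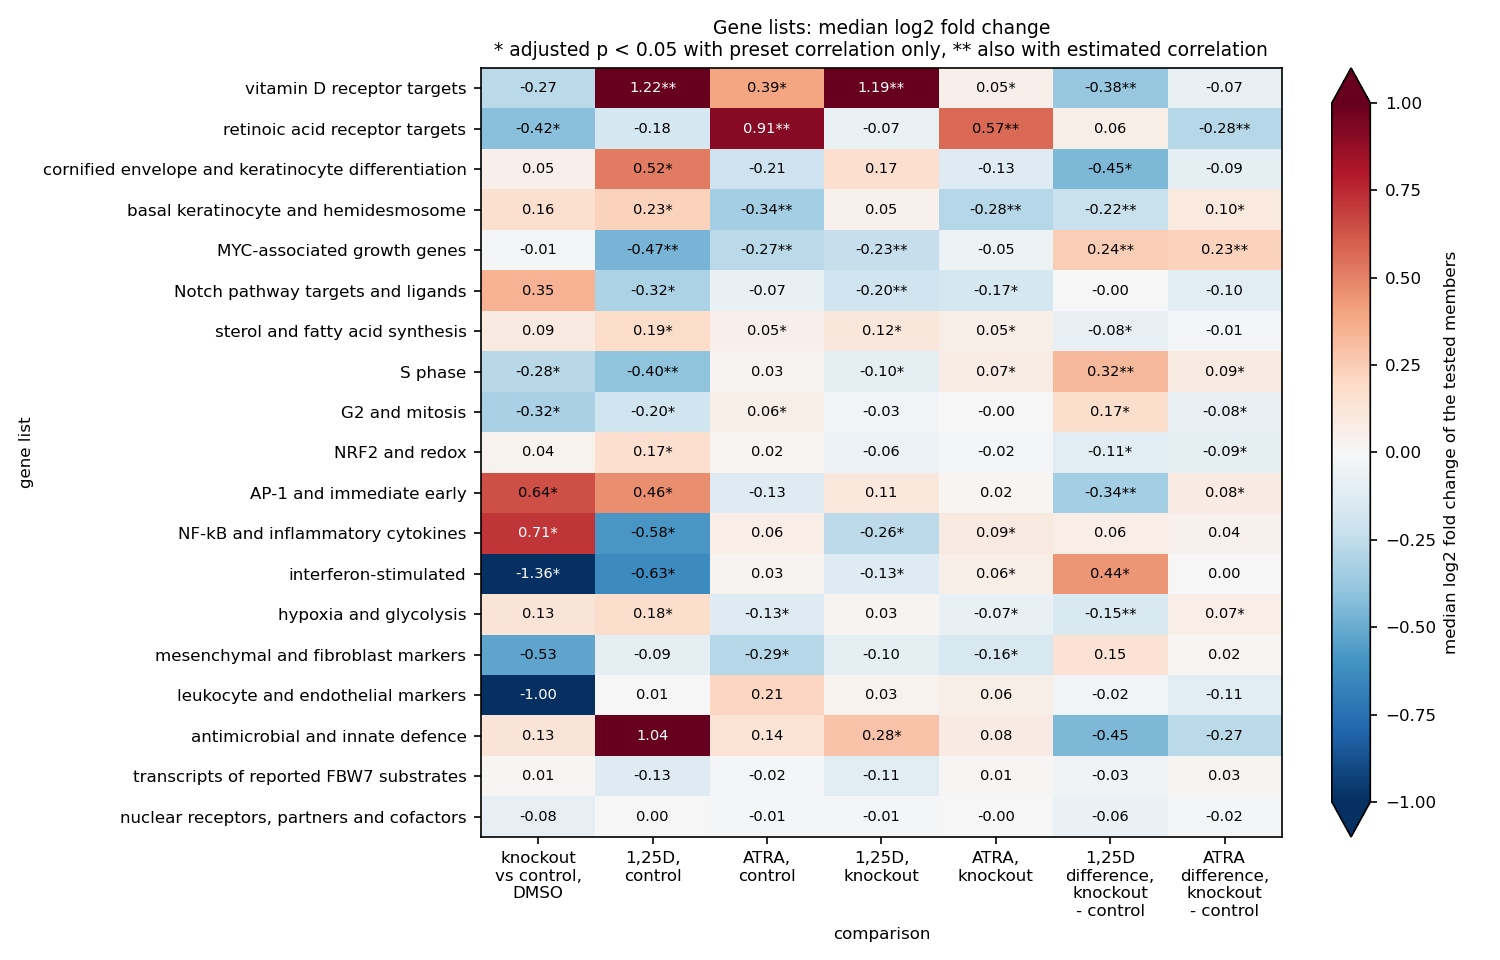
Median log2 fold change (colour) of the 19 gene lists in the 7 comparisons; 1 star marks a camera call with the preset correlation and 2 stars a call that also held with the estimated correlation. Vitamin D receptor targets have medians of 1.22 and 1.19 under 1,25D in control and knockout cells.

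In knockout cells the response to 1,25D included many of the genes named for control cells. CYP24A1 rose from 6.08 ± 0.330 to 526 ± 10.7 CPM (SD, n = 3), a log2 change of 6.43 ± 0.04, with COLEC12 (6.53 ± 0.35), SLCO1A2 (5.88 ± 0.08), CNR1 (5.19 ± 0.37) and CYP3A5 (5.03 ± 0.18). TRPV6, an epithelial calcium channel, went from 1 count to 99 (89.97-fold higher, counting interval 15.8 to 3589). SERPINB13 (-2.45 ± 0.16), OLR1 (-2.45 ± 0.07), IL24 (-2.34 ± 0.11) and WNT16 (-2.05 ± 0.33) fell, and so did MYC (-0.58 ± 0.03) and VDR (-0.44 ± 0.03). The largest edgeR adjusted p among these genes was 2.42e-06. Camera calls of 3 lists held with the estimated correlation. Of vitamin D receptor targets 28 rose, 2 fell and 5 were not called, or 30 and 2 over the list alone (median 1.19, camera adjusted p = 3.38e-19, and 0.00175 with estimated correlation). Of MYC-associated growth genes 2 rose, 51 fell and 5 were not called, or 3 and 52 over the list alone (median -0.23, camera adjusted p = 8.13e-19, and 0.00812 with estimated correlation). Of Notch genes 1 rose, 11 fell and 8 were not called (median -0.20, camera adjusted p = 0.000888, and 0.0207 with estimated correlation). The ligands JAG1 (-0.96) and JAG2 (-0.72) and the Notch feedback gene NRARP (-0.71) fell. The calls of 5 lists were lost. Of sterol synthesis genes 18 rose, 6 fell and 9 were not called, or 18 and 8 over the list alone (median 0.12, camera adjusted p = 0.00363, and adjusted p = 0.330 with estimated correlation). Of S phase genes 5 rose, 17 fell and 10 were not called, or 5 and 18 over the list alone (median -0.10, camera adjusted p = 0.00789, and adjusted p = 0.330 with estimated correlation). Of NF-kB genes 5 rose, 13 fell and 5 were not called (median -0.26, camera adjusted p = 0.0441, and adjusted p = 0.368 with estimated correlation). Of interferon-stimulated genes 2 rose, 12 fell and 16 were not called (median -0.13, camera adjusted p = 0.00789, and adjusted p = 0.655 with estimated correlation). Of antimicrobial genes 7 rose, 1 fell and 6 were not called, or 7 and 3 over the list alone (median 0.28, camera adjusted p = 0.0441, and adjusted p = 0.330 with estimated correlation). In this list CD14 (2.01) and the lipopolysaccharide receptor TLR4 (1.499) rose (edgeR, largest adjusted p 2.98e-15). The test pointed up for cornified envelope genes (median 0.17, mean -0.13), NRF2 genes (-0.06, 0.05) and nuclear receptors (-0.01, 0.07), whose median and mean differed in sign. There were 6579 called genes (3186 higher, 3393 lower), 427 and 201 of them by 2-fold or more, and 47.5% without overlap against 10% by chance. Of 5630 genes called in both cell types 5473 (97.2%) moved the same way.

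ATRA in knockout cells raised CYP26A1 from 0.0223 ± 0.0386 to 1.01 ± 0.254 CPM (SD, n = 3), a log2 change of 5.37 ± 0.65. All 4 counts of the knockout DMSO group lay in replicate 1, without which the rise was at least 39.8-fold, with 3 counts over the group as the floor. Rises were also seen in STRA6 (3.71 ± 0.11), ELF3 (3.23 ± 0.13), WNT16 (2.90 ± 0.19), ISLR2 (2.90 ± 0.07) and MMP12, a macrophage elastase (2.41 ± 0.21). NTSR1 (-2.05 ± 0.28), CASP14 (-1.88 ± 0.32) and IL24 (-1.77 ± 0.11) fell, KRT1 went from 75 counts to 1 (83.8-fold lower, counting interval 14.6 to 3353), and S100A8 from 9 to 0 (at least 3.35-fold lower, with 3 counts over the group as the floor). MYC rose slightly (0.11 ± 0.03). By edgeR the largest adjusted p among the genes with a log2 change was 0.00269. Camera called 2 lists with either correlation. Of retinoic acid receptor targets 18 rose, 2 fell and 10 were not called, or 18 and 3 over the list alone (median 0.57, camera adjusted p = 2.27e-14, and 0.0102 with estimated correlation), with DHRS3 at 1.94. Of basal keratinocyte genes 2 rose, 15 fell and 5 were not called, or 3 and 16 over the list alone (median -0.28, camera adjusted p = 2.57e-11, and 0.0160 with estimated correlation), with ITGA6 at -0.84. The MYC-associated list missed the threshold: 6 rose, 14 fell and 38 were not called, or 7 and 14 over the list alone (median -0.05, camera adjusted p = 0.0529). Calls upward with the preset correlation alone were those of 5 lists. Of vitamin D receptor targets 9 rose, 5 fell and 21 were not called, or 9 and 6 over the list alone (median 0.05, camera adjusted p = 0.0355, and adjusted p = 0.330 with estimated correlation). Of sterol synthesis genes 12 rose, 1 fell and 20 were not called, or 15 and 1 over the list alone (median 0.05, camera adjusted p = 7.67e-05, and adjusted p = 0.104 with estimated correlation), with SCD at 0.79. Of S phase genes 14 rose, 1 fell and 17 were not called, or 16 and 1 over the list alone (median 0.07, camera adjusted p = 0.000135, and adjusted p = 0.104 with estimated correlation). Of NF-kB genes 10 rose, 3 fell and 10 were not called (median 0.09, camera adjusted p = 0.0140, and adjusted p = 0.230 with estimated correlation), with CCL20 at 1.55. Of interferon-stimulated genes 8 rose, 2 fell and 20 were not called, or 8 and 3 over the list alone (median 0.06, camera adjusted p = 0.0396, and adjusted p = 0.645 with estimated correlation), with SAMD9 at 0.85. Calls downward with the preset correlation alone were those of 3. Of Notch genes 1 rose, 8 fell and 11 were not called (median -0.17, camera adjusted p = 0.00537, and adjusted p = 0.0734 with estimated correlation), with JAG1 at -0.57. Of hypoxia genes 4 rose, 10 fell and 14 were not called, or 4 and 11 over the list alone (median -0.07, camera adjusted p = 0.00275, and adjusted p = 0.103 with estimated correlation), with CA12 at -0.80. Of mesenchymal genes 2 rose, 10 fell and 14 were not called, or 2 and 11 over the list alone (median -0.16, camera adjusted p = 0.0236, and adjusted p = 0.173 with estimated correlation), with VIM at -0.72. The edgeR adjusted p was at most 3.61e-10 among the list members named. Antimicrobial genes had a median of 0.08 (0.17 with members near 0 counts at their counting estimate) with a mean of -0.29 and a test pointing up, and nuclear receptors a median just under 0 with a mean of 0.32 and a test pointing up. ATRA changed 4346 genes (2039 higher, 2307 lower), 200 and 97 by 2-fold or more, with 37.1% free of overlap against 10% by chance. Of 3449 genes called in both cell types 3391 (98.3%) moved the same way.

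The last question was whether the responses differ between knockout and control cells, and it was tested as the knockout response minus the control response. CYP24A1 gained less from 1,25D in the knockout, by a log2 difference of -2.40 ± 0.06 (edgeR adjusted p = 1.19e-28), on a DMSO level that was already lower (-0.69 ± 0.05, adjusted p = 2.16e-15). The bone morphogenetic protein BMP6 (-2.11 ± 0.20), the peptidoglycan sensor NOD2 (-2.13 ± 0.25), CASP14 (-2.12 ± 0.28), FAM131B (-2.13 ± 0.38), FAM83C (-2.06 ± 0.49) and GAP43 (-1.999 ± 0.29) also differed downward. CXCL10 (2.93 ± 0.41), TMEM52B (2.44 ± 0.22), PTPRZ1 (1.59 ± 0.13) and ANKRD1 (1.55 ± 0.14), which had fallen in control cells, differed upward, as did the growth factor FGF1 (1.81 ± 0.19) and the muscle coactivator MYOCD (2.34 ± 0.39). The largest edgeR adjusted p among these genes was 0.00150. For VDR the difference was 0.06 ± 0.04 (adjusted p = 0.383) and for MYC -0.08 ± 0.04 (adjusted p = 0.178), neither called, while RXRA (-0.14 ± 0.03) and JUN (-0.45 ± 0.04) differed downward (edgeR, largest adjusted p 0.00154). IFI44L (2.42) was called, but not without FBW7-knockout 1,25D replicate 2 (2.03, adjusted p = 0.0683), and FEZF1-AS1 (-1.85) is antisense to another gene and uncertain, since the strand setting of the counting is not given in the sources used here.

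For the lists, rose and fell here refer to the sign of the difference. Vitamin D receptor targets responded less in the knockout: 3 rose, 20 fell and 12 were not called, or 4 and 20 over the list alone (median -0.38, camera adjusted p = 6.20e-07, and 0.0238 with estimated correlation), with CDH1, E-cadherin, at -0.72. The MYC-associated and S phase lists had fallen under 1,25D in control cells and fell less in the knockout. Of MYC-associated genes 50 rose, 1 fell and 7 were not called, or 53 and 1 over the list alone (median 0.24, camera adjusted p = 6.13e-26, and 0.00204 with estimated correlation), with UNG at 0.55. Of S phase genes 30 rose, 0 fell and 2 were not called, or 31 and 0 over the list alone (median 0.32, camera adjusted p = 6.13e-26, and 0.000889 with estimated correlation), with MCM10 at 0.56. Another 3 lists differed downward. Of basal keratinocyte genes 1 rose, 16 fell and 5 were not called (median -0.22, camera adjusted p = 2.41e-10, and 0.0124 with estimated correlation), with LAMB3 at -0.51. Of AP-1 genes 1 rose, 15 fell and 8 were not called, or 1 and 16 over the list alone (median -0.34, camera adjusted p = 1.63e-10, and 0.00848 with estimated correlation), with DUSP5 at -1.07. Of hypoxia genes 2 rose, 10 fell and 16 were not called, or 2 and 13 over the list alone (median -0.15, camera adjusted p = 0.000163, and 0.0284 with estimated correlation), with the glucose transporter SLC2A1 at -0.73. These 6 calls held with the estimated correlation and 5 others did not. Of G2 and mitosis genes 24 rose, 0 fell and 6 were not called, or 26 and 0 over the list alone (median 0.17, camera adjusted p = 5.81e-13, and adjusted p = 0.0912 with estimated correlation). Of interferon-stimulated genes 24 rose, 0 fell and 6 were not called, or 24 and 1 over the list alone (median 0.44, camera adjusted p = 1.27e-11, and adjusted p = 0.0912 with estimated correlation). OAS3 was at 0.59. Of cornified envelope genes 2 rose, 10 fell and 14 were not called (median -0.45, camera adjusted p = 0.0336, and adjusted p = 0.245 with estimated correlation). Of sterol synthesis genes 2 rose, 12 fell and 19 were not called, or 2 and 13 over the list alone (median -0.08, camera adjusted p = 0.0116, and adjusted p = 0.245 with estimated correlation). Of NRF2 genes 2 rose, 13 fell and 10 were not called, or 2 and 15 over the list alone (median -0.11, camera adjusted p = 0.000214, and adjusted p = 0.0912 with estimated correlation), with SLC7A11 at -0.73. Over the list members named, the edgeR adjusted p was 1.92e-07 or lower. Several of these lists already differed in DMSO, with the sign opposite to the difference. Medians of knockout against control were -1.36 (interferon-stimulated), -0.28 (S phase), -0.32 (G2 and mitosis), 0.64 (AP-1), 0.16 (basal) and 0.13 (hypoxia). Vitamin D receptor targets had the same sign in both (-0.27). The difference contrast holds the same DMSO libraries, and the part of starting level was not tested for lists. Of lists not called, the leukocyte and endothelial list had a median of -0.02 with a mean of 0.20 and a test pointing up, and the substrate list -0.03 with 0.07 and a test pointing down. The difference was called for 4248 genes (1918 upward, 2330 downward; edgeR), 76 and 142 of them 2-fold or more. Mitochondrial shares in the 4 groups of this comparison were 3.31%, 3.85%, 4.24% and 4.62% (control DMSO, control 1,25D, knockout DMSO, knockout 1,25D).

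For ATRA, genes that differed downward included FAM131B (-3.07 ± 0.37), the hormone FGF19 (-1.94 ± 0.19), the guanine exchange factor DOCK8 (-1.80 ± 0.25), the nuclear receptor NR5A2 (-1.74 ± 0.26), TNFAIP2 (-1.72 ± 0.06) and ITGB3 (-1.62 ± 0.13). CXCL14 (1.72 ± 0.18), WNT16 (1.00 ± 0.25), MYC (0.33 ± 0.04) and VDR (0.22 ± 0.04) differed upward (edgeR, largest adjusted p among these genes 0.00399). CYP26A1 gave -3.53 ± 1.81 (adjusted p = 0.245), which was not called by edgeR though it was by DESeq2. No value is given without FBW7-knockout DMSO replicate 1, since 0 counts then remained in that group. Its DMSO level was 0.108 ± 0.0736 CPM in control and 0.0223 ± 0.0386 in knockout cells (-2.22 ± 1.10, edgeR adjusted p = 0.0902, called without FBW7-knockout DMSO replicate 1, at least 4.4-fold lower, adjusted p = 0.0271). Retinoic acid receptor targets responded less, where rose and fell again refer to the difference: 1 rose, 14 fell and 15 were not called, or 1 and 15 over the list alone (median -0.28, camera adjusted p = 6.41e-10, and 0.0230 with estimated correlation). CRABP2, a retinoic acid carrier, was at -0.83. The MYC-associated list fell less: 45 rose, 0 fell and 13 were not called, or 49 and 0 over the list alone (median 0.23, camera adjusted p = 1.46e-33, and 0.00126 with estimated correlation), with HSPD1 at 0.32. Both calls held with the estimated correlation, and 6 others did not. Of basal keratinocyte genes 9 rose, 1 fell and 12 were not called, or 10 and 1 over the list alone (median 0.10, camera adjusted p = 1.69e-06, and adjusted p = 0.0790 with estimated correlation), with ITGA6 at 0.35. Of S phase genes 10 rose, 0 fell and 22 were not called, or 11 and 1 over the list alone (median 0.09, camera adjusted p = 6.62e-06, and adjusted p = 0.0791 with estimated correlation). Of AP-1 genes 7 rose, 1 fell and 16 were not called, or 8 and 2 over the list alone (median 0.08, camera adjusted p = 0.0208, and adjusted p = 0.382 with estimated correlation). Of hypoxia genes 8 rose, 3 fell and 17 were not called, or 9 and 3 over the list alone (median 0.07, camera adjusted p = 0.0130, and adjusted p = 0.174 with estimated correlation), with NDRG1 at 0.45. Of G2 and mitosis genes 0 rose, 5 fell and 25 were not called, or 0 and 7 over the list alone (median -0.08, camera adjusted p = 5.72e-05, and adjusted p = 0.382 with estimated correlation). Of NRF2 genes 1 rose, 5 fell and 19 were not called, or 1 and 8 over the list alone (median -0.09, camera adjusted p = 0.0259, and adjusted p = 0.382 with estimated correlation). Among these list members the largest edgeR adjusted p was 1.02e-08. Cornified envelope genes (-0.09, mean -0.27) had a test pointing up, and interferon-stimulated genes a median just above 0 with a mean of -0.09. The difference was called for 2458 genes (1308 upward, 1150 downward; edgeR), 19 and 73 by 2-fold or more. The largest upward value belonged to CLIC1 (10.5), which had 9, 7 and 1018 counts in the control DMSO libraries and was at 5.21 without control DMSO replicate 3 and 4.54 without FBW7-knockout ATRA replicate 2. Its call was lost without any one library (adjusted p = 0.0835 to 0.559) except control DMSO replicates 1 and 2 and FBW7-knockout ATRA replicates 1 and 3.

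Both responses were on the whole smaller in the knockout. Over 9737 genes that responded to 1,25D on average of the 2 cell types, 79.0% had a weaker response in the knockout (3388 called weaker and 297 stronger; limma fry, p of 5.24e-12), and over 896 genes changed 2-fold or more on average the median size was 1.75 in control and 1.29 in knockout cells. For ATRA 74.6% of 7943 genes were weaker (1856 called weaker, 190 stronger; limma fry, p of 6.32e-10), and the median size over 474 genes was 1.53 against 1.22. The 331 of these that ATRA raised were weaker for 73.7% (medians 1.60 and 1.21) and the 143 that it lowered for 58.04% (medians -1.32 and -1.24). With 1,25D these shares were 81.1% of 581 raised and 74.3% of 315 lowered genes. fry asks whether the genes of a set move on balance one way and does not compare them with other genes. In 21 simulations with 1000 genes changed alike in both cell types (1.5-fold, 16132 genes), 50.01% were weaker on average, with a range of 47.6% to 54.3%. Of these simulations 2 had a fry p below 0.05 (0.00056 and 0.0468). Correlation between genes and a knockout effect were not simulated.

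**Figure D5:**
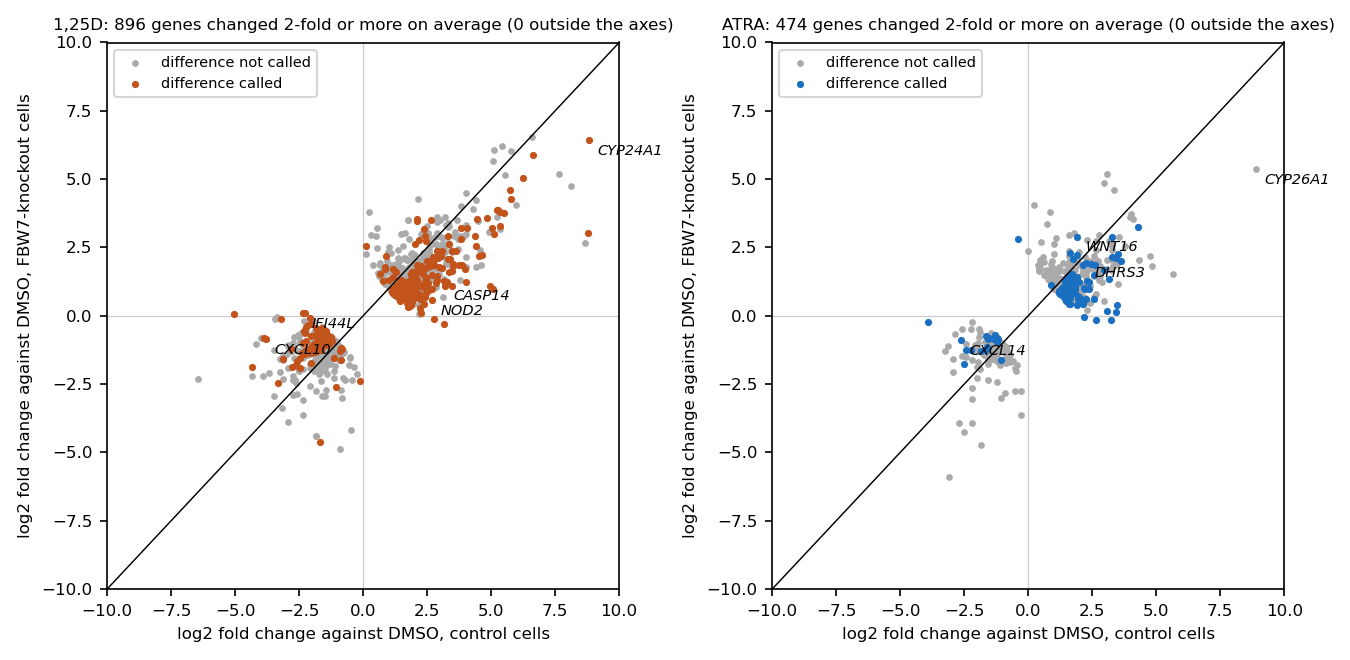
Log2 fold change in control cells (x axis) against knockout cells (y axis) for the 896 genes changed 2-fold or more on average by 1,25D and the 474 changed so by ATRA, with 1 point per gene, coloured where the difference was called. By the sign of the difference the response was weaker in the knockout for 78.7% and 69.0% of those shown, genes that crossed 0 included.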

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

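Chosen after the result was seen were the regional-block position test, the GC-content and length trend, the non-responding-fraction test, the test of genes with like DMSO levels, the shared-copies test, the sampling-noise test, removal of 20-Mb window medians and thinning of the libraries. What set apart the differences in ligand response given below was a test of the difference between control and FBW7-knockout cells itself. They were called for 4248 genes with 1,25D and 2458 with ATRA. Other splits of the libraries were counted in fits of only the groups compared. For the 1,25D difference 4 of 100 splits drawn from 200, the real one included, gave as many genes (4243, highest other 6315), and for ATRA 4 of 100 (2346, highest other 4182). A first draw of 40 gave 3 for each, a share of 0.075, so the draw mattered. The 10 splits that exchange every DMSO and ligand library of the control cells all gave as many (6043 to 9716 for 1,25D, 3650 to 7785 for ATRA), and with the real split these are 11 of 200, a share of 0.055. These splits leave the 2 ligand responses in the contrast, so their counts do not show what chance gives. The share therefore cannot decide on chance for either ligand, and no conclusion is drawn from it. In 1 of these 10 splits the contrast becomes the sum of the 2 responses, and the other 9 also exchange 1 DMSO and 1 ligand library of the knockout cells. For the contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split, which was the 1 split as large in each, gave 11048 genes for the knockout (highest other 0), 9457 and 7480 for 1,25D and ATRA in control cells (0 and 1), and 6343 and 3935 in knockout cells (0 and 1).

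The effect of the knockout ran in blocks along the chromosomes. In DMSO 21 of 147 windows of 20 Mb had at least 80% of their genes shifted one way, against 1 in the highest shuffle and 0 for the 1,25D response of control cells, and the count was still 21 after removal of a trend on GC content and length. That trend took 0.257% of the variance between genes, against 10.5% by window, which argues against such a bias. With window medians subtracted, 8344 genes were called against 8678 of the same 10948 before, 7614 of them in both. Shifts shared by whole 20-Mb windows thus did not account for most calls, while smaller segments were not tested. Lists called in the knockout kept the sign of their medians over the members in these windows. Before and after subtraction these were -1.36 and -1.44 (interferon-stimulated), -0.28 and -0.30 (S phase), and -0.32 and -0.36 (G2 and mitosis). The others were -0.34 and -0.27 (retinoic acid receptor targets), 0.67 and 0.58 (AP-1), and 0.71 and 0.73 (NF-kB). A difference in copy number between the 2 cell populations may underlie the blocks, as may any other regional difference, and the design cannot part either from loss of FBW7.

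Responses were weaker in knockout cells for 79.0% of the genes responding to 1,25D and 74.6% of those responding to ATRA, but for 58.04% of the 143 genes that ATRA lowered 2-fold or more. Depth did not account for the 1,25D pattern, with 78.7% after thinning. For genes raised 2-fold or more on average, a higher starting level did not account for all of either ligand's pattern. Of 85 such genes with like DMSO levels (within 0.2 log2) 91.8% responded less to 1,25D (85.0% of 40 for ATRA). Lowered genes and genes raised by less than 2-fold, which are most of those in the shares above, were not tested in this way. For 1,25D a share of unresponsive cells did not account for all of the weakening. OLR1 limits that share to 20.2%, and 246 of 581 raised genes lay further below what it would leave. A weaker action of both receptors in FBW7-deficient cells may explain the pattern, as may any other difference between the 2 populations, which the design confounds with the knockout. In simulations without a difference the fry test passed 0.05 in 2 of 21 draws, so its p-values may be too small.

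Some abundant genes differed many-fold between replicates, among them 3 with large upward ATRA differences. CLIC1 (10.5) had 9, 7 and 1018 counts in control DMSO and 7, 1131 and 6 in knockout ATRA libraries, YTHDC1 (6.24) 1271, 54 and 596 in control DMSO, and ITPK1 (2.90) 297, 497 and 1527 in knockout ATRA. The CLIC1 call was lost without any one of 8 libraries (adjusted p 0.0835 to 0.559, at 5.21 without control DMSO replicate 3 and 4.54 without FBW7-knockout ATRA replicate 2; kept without control DMSO replicate 1 or 2 or FBW7-knockout ATRA replicate 1 or 3), that of YTHDC1 without any of 10 (0.0524 to 0.105; kept without control DMSO replicate 2 or FBW7-knockout ATRA replicate 2) and that of ITPK1 without any of 10 (0.0553 to 0.138; kept without control DMSO replicate 2 or FBW7-knockout ATRA replicate 1). In all 71 genes were so erratic, against 0 in the highest of 100 Poisson draws at the same means, which argues against sampling noise. SPARC, from the mesenchymal list, was among them, at 18.2, 20.7 and 0.252 CPM in the control ATRA libraries. SFRP2, also erratic, was at 1.28, 2.64 and 0.0133 CPM there. In the control DMSO libraries SPARC was at 19.1, 16.8 and 45.1 CPM and SFRP2 at 0.925, 1.03 and 2.81, so the 2 varied together. Which cells held these transcripts was not tested, and mesenchymal values of control cells may depend on single libraries. Genes of the major histocompatibility region, which has alternate copies in the reference, were over-represented (10 of 33, against 0.472% of the other genes; odds ratio 91.3, Fisher's exact test p = 1.07e-15), so assignment of reads to near-identical copies may be a source. Most of the 71 lie elsewhere, some close together, such as CISD3, PCGF2, PSMB3 and PIP4K2B on chromosome 17 and GSDMD, MROH6, NAPRT and EEF1D on chromosome 8. The test covered the histocompatibility region alone, so it cannot say whether shared copies account for these other genes. No biological explanation was tested.

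For 1,25D the list medians of the difference were -0.38 for vitamin D receptor targets, -0.22 for basal keratinocyte genes, 0.24 for MYC-associated genes, 0.32 for S phase, -0.34 for AP-1 and -0.15 for hypoxia. Calls lost with an estimated correlation were those of cornified envelope (-0.45), sterol synthesis (-0.083), G2 and mitosis (0.17), NRF2 (-0.11) and interferon-stimulated genes (0.44). Genes that differed upward were CXCL10 (2.93), TMEM52B (2.44), IFI44L (2.42; 2.03, adjusted p = 0.0683 without FBW7-knockout 1,25D replicate 2), MYOCD (2.34), FGF1 (1.81), SYNPO2 (1.65), PTPRZ1 (1.59) and ANKRD1 (1.55). Downward were CYP24A1 (-2.40), FAM131B (-2.13), NOD2 (-2.13), CASP14 (-2.12), BMP6 (-2.11), FAM83C (-2.06), GAP43 (-1.999), FEZF1-AS1 (-1.85, uncertain as antisense to another gene), RXRA (-0.14) and JUN (-0.45).

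For ATRA the list medians of the difference were -0.28 for retinoic acid receptor targets and 0.23 for MYC-associated genes. Calls lost with an estimated correlation were those of basal keratinocyte (0.10), S phase (0.0931), G2 and mitosis (-0.0842), NRF2 (-0.0872), AP-1 (0.0826) and hypoxia genes (0.0679). Genes that differed upward were CXCL14 (1.72), WNT16 (0.9954), MYC (0.33) and VDR (0.22). PLCD4 (1.16) was not called without control DMSO replicate 1 (1.05, adjusted p = 0.0536), control ATRA replicate 2 (0.91, adjusted p = 0.114) or FBW7-knockout ATRA replicate 3 (0.72, adjusted p = 0.291). CXCL10 (1.04) was not called without FBW7-knockout DMSO replicate 1 (0.79, adjusted p = 0.0766) or 2 (1.06, adjusted p = 0.0572) or FBW7-knockout ATRA replicate 1 (0.87, adjusted p = 0.0814). KRT16 (0.96), which may share reads with other keratins, was not called without control DMSO replicate 3 (0.89, adjusted p = 0.059), control ATRA replicate 1 (0.85, adjusted p = 0.0722) or 3 (0.84, adjusted p = 0.0856), FBW7-knockout DMSO replicate 2 (0.94, adjusted p = 0.054) or FBW7-knockout ATRA replicate 1 (0.95, adjusted p = 0.0513) or 3 (0.92, adjusted p = 0.0635). CCNE1 (0.30) was called without control ATRA replicate 3 and lost without any of the other 11 libraries (adjusted p 0.0502 to 0.111). Downward were FAM131B (-3.07), FGF19 (-1.94), DOCK8 (-1.80), NR5A2 (-1.74), TNFAIP2 (-1.72), ITGB3 (-1.62), SELENOP (-1.56) and CCDC80 (-1.525).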

How the results depend on the processing

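Removal of 20-Mb window medians, thinning, RLE scaling of the weakening test and the 0.01 threshold for named genes were chosen after the results were seen. No called direction was reversed under any alternative run. Counts of called genes stayed within 1.5 times the reported ones with DESeq2 (11132, 9230, 7241, 6383, 4152, 4190 and 2501 for knockout, 1,25D and ATRA in control cells, 1,25D and ATRA in knockout cells, and the differences for 1,25D and ATRA), RLE size factors, both filters and fits of only the groups compared. A test against a 1.5-fold change left 2779, 1431, 626, 601, 224, 93 and 21 genes in the same order, and an adjusted p below 0.01 left 1511 for the ATRA difference, both because the demand is stricter. With the replicate number as a block the counts were 11460, 9583, 7628, 6743, 4503, 4458 and 2671. The replicate numbers showed a weak relation. Of 45 same-numbered pairs 19 had a correlation of deviations above 0.1 (mean 0.0737, lowest -0.133, highest 0.211). The 90 other pairs had a mean of -0.0367 and a highest value of 0.232. Deviations were taken from group means, which ties the mean of the other pairs to that of the same-numbered ones, so it is no separate evidence. Of 18 libraries 14 were closest to their own number, so a shared replicate effect is not excluded. The labels do not pair the samples, and the main fit did not use the numbers. The block changed no count by over 1.5 times and otherwise ended 2 list calls and 3 calls of named genes and added 1 and 3. Leaving out each library gave 10845 to 11017 genes for the knockout, 8810 to 9036 and 6595 to 6952 for 1,25D and ATRA in control cells, 5857 to 6141 and 3598 to 3911 in knockout cells, 3767 to 4238 and 2040 to 2518 for the differences, and 3156 to 3517 genes shared by the ligands, with weaker responses at 77.5% to 80.3% (1,25D) and 72.7% to 76.2% (ATRA). For named genes it ended a call 177 times and added one 11 times, and 4762 stayed on their side of the threshold. The stricter threshold of 0.01 ended 39 calls of named genes. No filter ended 13, the groups compared alone 9 (1 added), DESeq2 3 (3 added) and RLE 1, where the cause was not tested. Of 133 list tests, 45 calls were lost with an estimated correlation, 2 with only the groups compared, and 1 with RLE (2 added). RLE moved the median of all genes by -0.0113 to 0.00707. Of 95 list medians 22 had members near 0 counts, which moved the median by 0.13 at most at their counting estimate, with 0 changes of sign. At this depth and spread small changes were not all found: of the smallest simulated changes 78% were recovered in the 1,25D response and 56% in its difference.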

Other observations

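The 2 MYC mRNA tests below were chosen after the result was seen. Some genes, picked from the lists after their values were seen, went opposite ways under the 2 ligands, although retinoic acid receptor targets as a list were not called under 1,25D (median -0.18, camera adjusted p = 0.240). In control cells DHRS3 was at -2.05 under 1,25D and 2.26 under ATRA, CRABP2 at -1.68 and 1.16, RARB at -3.50 and 1.32, and MYB, a transcription factor, at -2.20 and 1.76. DHRS3 kept both directions in the knockout (-1.74 and 1.94). RARB was at -2.94 under 1,25D there, while its ATRA response was not called (0.59, adjusted p = 0.254) and neither was the difference in that response (-0.73, adjusted p = 0.320), which was called without FBW7-knockout DMSO replicate 1 (-1.19, adjusted p = 0.0401). CYP27B1, the enzyme that makes 1,25D, was higher in the knockout (1.33) and fell under ATRA in control (-0.67) and knockout cells (-0.39). CRABP2 differed in both responses, by 0.85 for 1,25D and -0.83 for ATRA.

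The antimicrobial and innate defence list was not called in the knockout (camera adjusted p = 0.868) or under ATRA in control (0.370) or knockout cells (0.899), and only single members, picked in the same way, are given here. LCN2 was at -2.79 in the knockout and rose under ATRA in control cells (1.153), with a difference in the ATRA response of -0.79. S100A9 was lower in the knockout (-2.08) and TLR4 higher (1.39), and TLR4 rose further under ATRA in control (0.98) and knockout cells (0.67). These values are from edgeR's quasi-likelihood test, with an adjusted p below 0.05 each.

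MYC-associated growth genes fell less under both ligands in knockout cells, and a smaller fall of MYC mRNA is a candidate explanation. Under 1,25D the difference in the MYC response was -0.0775, with -0.16 to 0.01 as 2 SE on either side, which argues against a smaller fall of the mRNA. Under ATRA the difference was 0.33 (0.25 to 0.41), the direction that explanation needs. MYC protein, which FBW7 is reported to degrade, was not analysed here, so its part in either response stays open.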
